A study of Saccharomyces cerevisiae with 25 samples.

How the data were processed

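RNA from 25 yeast samples, 1 in high phosphate and 24 taken every 15 min after transfer to medium without phosphate, was analysed. Per the labels' protocols, cells were frozen in liquid nitrogen, lysed enzymatically in 96-well plates, extracted with a kit of that plate format, and the cDNA was sequenced on an Illumina instrument. Per the submitters' processing notes, reads were aligned with Bowtie to genome build R64. The version of the aligner, the counter, the treatment of reads that map to several places, strand and any molecular identifiers are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense genes are uncertain.

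The deposited file holds log2 values made by the authors, 1 column per sample, for 6701 lines, of which 51 carry no gene name and no value, which left 6650 named genes. The deposited log2 values, taken back to the linear scale, sum to 1000000 in each column, so they are reads scaled to that sum (RPM) on a log2 scale. They are not ratios to the high-phosphate sample, although the design text speaks of a normalization to the first time. A gene has no value in a sample where it fell below a floor, and 95.97% of the values below 400 units were whole multiples, within 0.01, of the smallest value in their column divided by 10 (94.88% to 97.36% over the columns). The floor was taken as 10 reads, and depth as 1000000 divided by what 1 such read is worth, which gave 209394 to 1737019 reads per library. These recovered reads describe depth, counting noise and weights only. A count model was not run on them, because the deposited unit is log2. Of the named genes 3109 had a value in all 25 samples and 1058 in none, and 5964 matched the reference annotation of build R64, from which coordinates were taken. The counting SD at the floor was 0.46 log2 units. Such limits cover counting error only, since reads from amplified libraries are not independent molecules. A gene without a value is called not listed, since it can lie anywhere below the floor.

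Each time had 1 library, so 4 neighbouring times stood in for replicates. The high-phosphate sample entered no test. A gene was tested when it had at least 3 values in each of the 6 windows, which left 4535 genes, and 1057 genes were listed somewhere but not tested. The tests, the window limits, the gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. limma 3.58.1 in R 4.3.3 fitted the 6 window means to the log2 values with no pseudocount (lmFit, and eBayes with trend and robust), and the contrasts were 315 to 360 minus 15 to 60 min and each window minus the one before. A natural cubic spline of time with 4 degrees of freedom was tested by the limma F test. Adjusted p-values are Benjamini-Hochberg values over all genes tested within a contrast, two-sided, with a threshold of 0.05, and for lists also adjusted over the list alone. Against the high-phosphate sample a gene counted when the mean of a window lay at least 1 log2 unit away and all 4 samples lay on that side. No p-value was given there, and medians of lists were set against 10000 random lists of the same size matched on expression. The level used for matching was the mean of the high-phosphate sample and the window itself. Members of the list were not taken out of the genes drawn from.

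The lists, 35 in number, comprised the PHO regulon and its parts for phosphate uptake, polyphosphate, secreted acid phosphatases and internal phosphatases; PHO signalling components, most of them outside that regulon; low-affinity phosphate transporters; ribosomal proteins; ribosome biogenesis; the induced environmental stress response; trehalose and glycogen; glycolysis; hexose transporters; gluconeogenesis with the glyoxylate cycle and fatty acid oxidation; the TCA cycle and respiration; Gcn4 amino acid synthesis; sulfur and methionine; nitrogen catabolite repression; purine synthesis; phospholipid synthesis; ergosterol; the zinc and iron regulons; histones; G1/S genes; G2/M and M/G1 genes; autophagy and vacuolar proteases; the proteasome; heat-shock chaperones; meiosis and sporulation; genes specific to each mating type; the pheromone response; the genes deleted in the strain; and housekeeping genes. Members are shared by some lists, HSP26 by the stress response and the chaperones and PHM8 by the PHO regulon and the stress response among them. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. These last 2 used the members listed in all 24 no-phosphate samples. fry asks whether the genes of a list move on balance in one direction and does not compare them with other genes.

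Named genes were the PHO regulon members, the 10 highest and 10 lowest changes between 15 to 60 and 315 to 360 min among genes past the threshold whose 4 late samples all lay beyond the 4 early ones, the 3 highest and 3 lowest past the threshold in each successive contrast, the 5 highest and 5 lowest against high phosphate at 15 to 60 min, and up to 4 members of each other list with the largest change in size. The midpoint time is the first time, by linear interpolation of a running median over 3 points, at which a course had covered 50% of the way from the high-phosphate value to its highest value, or its lowest for a list that fell, for courses that span at least 1 log2 unit. The range given with it comes from leaving out each sample in turn. This range shows only how far the midpoint depends on single samples of 1 course, and is not an error. Its summary over 19 PHO genes listed in every sample was chosen after the data were seen, as was the reporting of the ribosomal protein time.

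The late contrast, the spline, the rule for 2-fold changes and the midpoint time were tested on simulated data. The list tests, the random lists and the successive contrasts were not. With 200 genes changed among the real expression levels and depths, the late contrast found 27 of 61 genes changed 1.5-fold, 51 of 55 changed 2-fold and 49 of 49 changed 4-fold, with 7 false calls among 134 (4236 genes tested). The spline found 15 of 57, 46 of 55 and 52 of 52, with 6 false calls among 119 (4288 genes tested). With no gene changed, neither made a call among 4338 genes. In these runs the noise added to counting had the same SD for every gene, below the fitted residual SD. It was independent between samples and between genes, and far fewer genes changed than were called in the real data. The rates of recovery and of false calls hold for that setting and are not error rates for serial samples of 1 course. The rule for 2-fold changes found 97% of genes raised and 96% of genes lowered 3-fold and counted 0 of 5004 unchanged genes (5204 genes run). In that run all genes had the same noise, an SD of 0.24 log2 units. This is below the counting SD of 0.46 at the floor, so the run says little on false calls among low genes. Midpoint times of simulated courses came out 1.4 to 6.8 min late on average, with an SD of up to 19 min.

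The alternatives were quantile normalization, median centring, other filters on low values (none, a floor of 50 reads, genes listed in all samples), a fit without trend and robustness, whitening for serial correlation, array weights, other widths of the windows, a fit of the 8 samples compared, other splines, and leaving out each sample in turn. For the comparison with high phosphate they were another baseline and thresholds of 1.5-fold and 4-fold, and for midpoints other smoothing, shares, scales and baselines. Leaving out samples in the successive contrasts, leaving out 120 min or 120 and 135 min together, setting unlisted values to the floor and weights from recovered reads were added after seeing the data. Alternatives on a pseudocount and on count scaling were not run, since the values are log2. Gene length and GC content came from the R64 annotation. Permutation tests used 100000 draws, or all orders where fewer than 10 samples entered. Steps outside limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Whether the libraries were prepared in more than 1 batch is not given in the sources used here.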

Results

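Transcript levels were measured by RNA sequencing in BY4741, a haploid laboratory strain of budding yeast of mating type a that carries deletions of HIS3, LEU2, MET17 and URA3. Cells taken from medium rich in phosphate were moved to medium without phosphate, and the course was followed from 15 to 360 min in steps of 15 min. The data comprise 25 libraries, of which 1 was taken at 0 min in high phosphate and 24 came from the no-phosphate medium, with 1 library for each time. The 24 later samples were treated as 6 windows of 4 neighbouring times, 15 to 60, 75 to 120, 135 to 180, 195 to 240, 255 to 300 and 315 to 360 min. Recovered depth ran from 209394 reads at 120 min to 1737019 reads at 75 min, with a median of 804867. The 120 min library listed 3261 genes, whereas the other 24 libraries listed 4325 to 5392. At the smallest value that the files list, counting alone gives a log2 SD of 0.46. All p-values measure only the spread between neighbouring serial samples of 1 course, which includes true change within a window and no spread between separate cultures.

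**Figure D1:**
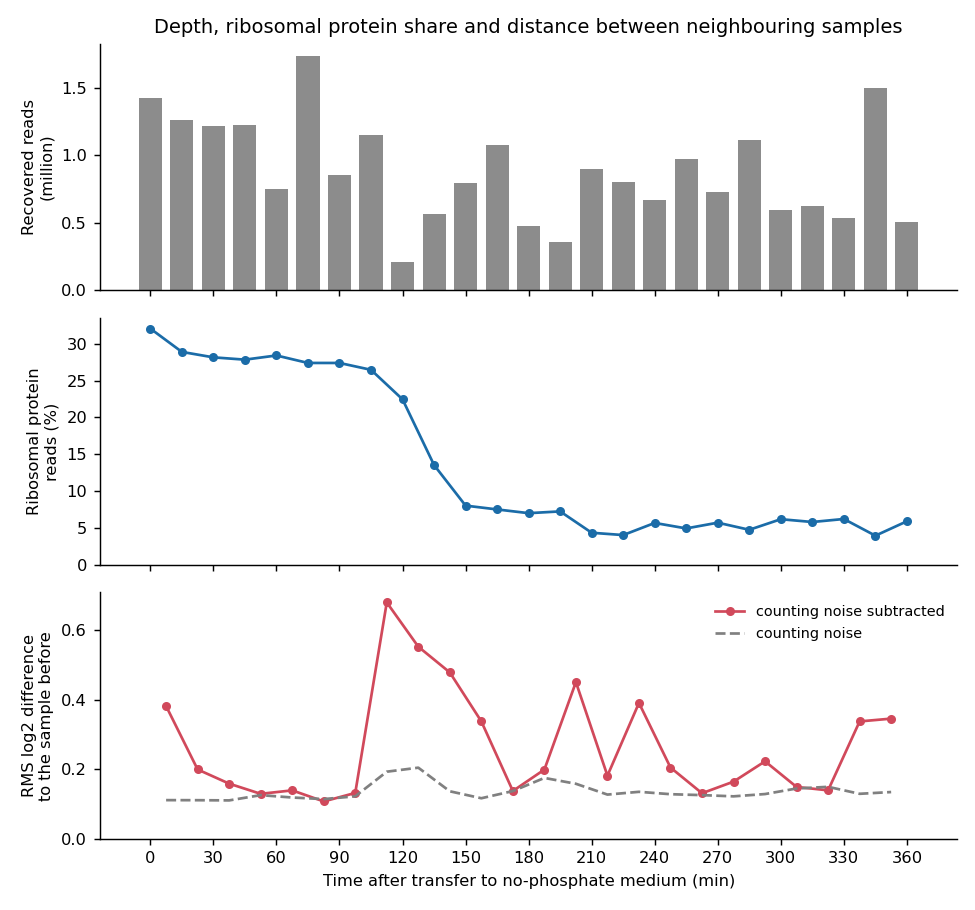
Recovered reads (bars), the percentage of reads on ribosomal protein genes (blue points) and the root mean square log2 difference to the sample before (red points with counting noise subtracted, grey dashes for counting noise) are plotted against time in min for all 25 libraries. The ribosomal protein percentage goes from 26.5% at 105 min to 8.01% at 150 min, and the largest difference between neighbours, 0.68, lies between 105 and 120 min.

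HIS3, LEU2, MET17 and URA3, the 4 genes deleted in BY4741, were listed in none of the 25 libraries. STE2, the receptor for alpha factor, was listed in all 25 libraries at 8.69 to 9.22 log2 RPM (reads scaled to a library sum of 1000000). The a-factor genes MFA1 and MFA2 reached 11.21 and 11.24. Of the genes specific to the other mating type, STE3, the a-factor receptor, was listed in 24 libraries with 13 to 52 reads, SAG1 in 17 libraries with 10 to 28 reads, and MF(ALPHA)1 in 6 libraries with 10 to 21 reads, while MF(ALPHA)2 was listed in none. STE3 was the 1 member of this list that could be tested between 15 to 60 and 315 to 360 min, and its change of 0.11 (SE 0.23) did not pass the test (limma adjusted p = 0.722), nor did it when adjusted over the list alone.

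The first comparison set each window against the high-phosphate library and asked which genes had moved at least 2-fold, with all 4 samples of the window on the same side. Within 15 to 60 min the 5 genes furthest above high phosphate were SPL2, a regulator of phosphate transport, RTC3, VTC3, a subunit of the vacuolar polyphosphate polymerase, PHO84, the high-affinity phosphate transporter, and PHO12, a secreted acid phosphatase. Their mean log2 ratios were 2.77 ± 0.77 for SPL2, 2.47 ± 0.39 for RTC3, 2.26 ± 0.16 for VTC3, 2.25 ± 0.19 for PHO84 and 2.16 ± 0.61 for PHO12 (SD over the 4 samples of the window). At 15 min PHO84 already stood 1.97 and VTC3 2.03 log2 units above high phosphate. The 5 genes furthest below were FRE1, a metal reductase, at -1.88 ± 0.51, YLR413W at -1.43 ± 0.30, MAE1, the mitochondrial malic enzyme, at -1.38 ± 0.18, DBP2, an RNA helicase, at -1.27 ± 0.54, and AAH1, an adenine deaminase, at -1.26 ± 0.19 (SD, n = 4). Of the PHO regulon, the genes controlled by the transcription factor Pho4, 12 of the 19 members compared were at least 2-fold higher, and the median of the list was 1.13, at percentile 100 among 10000 random lists matched on expression.

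Other groups stood apart from random lists of their size in the same 15 to 60 min window. The median log2 ratio was 0.82 for genes induced in the environmental stress response (19 of 46 compared at least 2-fold higher, percentile 100) and 0.86 for trehalose and glycogen metabolism (4 of 17, percentile 100). It was 0.66 for heat-shock chaperones (5 of 22, percentile 100) and 0.64 for autophagy and vacuolar proteases (3 of 16, percentile 100). The proteasome had a median of 0.36 with none of 32 at 2-fold (percentile 100), sulfur and methionine 0.42 (percentile 99.98), respiration 0.27 (percentile 99.98) and glycolysis 0.31 (percentile 99.93). Ribosome biogenesis genes had a median of -0.68, at percentile 0, with 5 of 77 at least 2-fold lower. Ribosomal protein genes had a median of -0.23, against -0.15 for the random lists, at percentile 0.055, and none of the 139 reached 2-fold. The iron regulon had a median of -0.34 at percentile 0.09, Gcn4 amino acid synthesis -0.18 at percentile 0.45 and histones -0.31 at percentile 0.5. The baseline was a single library, so these ratios have no replicate check and no p-value. Random lists were drawn gene by gene, whereas members of a list can move together, so the percentiles are not error rates. The draws could also take members of the list itself, so the ribosomal protein genes were set in part against themselves. Random lists for other abundant genes can hold ribosomal protein genes. Their random medians were -0.13 for glycolysis and -0.10 for histones, and the percentiles are relative to these values.

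The number of genes at least 2-fold from high phosphate was 142 of 4737 in the 15 to 60 min window (117 higher and 25 lower) and 168 of 3235 at 75 to 120 min (155 higher and 13 lower). It was 920 of 4441 at 135 to 180 min (616 higher and 304 lower), 1058 of 4231 at 195 to 240 min (800 and 258), 1205 of 4768 at 255 to 300 min (910 and 295) and 1276 of 4545 at 315 to 360 min (995 and 281). All 19 PHO regulon members compared were at least 2-fold higher in each of the 4 windows from 135 min on, and 17 of 19 were at 75 to 120 min. The median gene itself lay 0.02 to 0.07 log2 units above high phosphate from 15 to 105 min and 0.26 to 0.43 above it from 120 min on, among 3109 genes listed in all samples. With each sample centred on its median gene, the split of higher against lower was 108 and 35, 111 and 27, 341 and 475, 425 and 438, 544 and 497, and 591 and 523 in the 6 windows. Against the 15 min sample in place of the high-phosphate library, 41 genes counted in the first window and 66 in the second. The 120 min library decided which genes could be compared at 75 to 120 min, where 119 of 4898 genes counted without it (107 higher and 12 lower).

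The order in which PHO genes rose was described by the midpoint time, at which the smoothed log2 course had covered 50% of the way from high phosphate to its highest value. The earliest were VTC3 at 11.8 min (11.7 to 21.2 when each sample was left out in turn), PHO86 at 13.2 min (12.8 to 22.7), VTC4 at 13.8 min (13.6 to 23.1), PHO84 at 14.8 min (14.6 to 25.3) and SPL2 at 20.3 min (19.9 to 23.1). VTC2, PHO12, PHO11 and VTC1 followed at 23.8, 25.7, 36.4 and 39.6 min, and PHO81, the inhibitor of the Pho80 and Pho85 kinase complex, and HOR2 stood at 49.4 and 49.7 min. PHO89, a sodium-coupled phosphate transporter, reached its midpoint at 84.6 min, PHM6 at 89.9 min and PHO5, the main secreted acid phosphatase, at 94.8 min. Later still were GDE1 at 103 min, PHM8 at 108 min, PPN1 at 111 min and KCS1 at 116 min. PHO8, the vacuolar alkaline phosphatase, had a midpoint of 105 min, which was 39.2 min with a single sample left out. The median of these 19 genes was 49.4 min (39.6 to 58.3). As lists, phosphate uptake (3 genes) reached its midpoint at 20.5 min and polyphosphate metabolism (5 genes) at 34.4 min. Secreted acid phosphatases (3 genes) stood at 36.4 min and internal phosphatases (4 genes) at 99.6 min. Each is the midpoint of a median course over few genes, whose own midpoints can lie far apart. In the uptake list PHO84 and SPL2 stood at 14.8 and 20.3 min but PHO89 at 84.6 min. Among the acid phosphatases PHO12 and PHO11 stood at 25.7 and 36.4 min but PHO5 at 94.8 min.

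Values under 15 min were interpolated before the first no-phosphate sample. Midpoints of simulated courses had an SD of up to 19 min, so the order of genes with close midpoints is not settled. The midpoint depends on the scale, and on linear ratios the median of the 19 genes was 110 min, with PHO84 at 99.6, VTC3 at 40.9, SPL2 at 49.0, PHO5 at 129 and PHO89 at 141 min. GIT1, a transporter of glycerophosphoinositol, was not listed at 0 min and CTF19 was listed in no sample, so neither has a midpoint. PHM7 was listed in 6 samples and its value of 259 min is not a reliable one. PHO11 and PHO12 are near-identical copies, as are PHO5 and its neighbour PHO3 in part, so reads could be split among them.

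**Figure D2:**
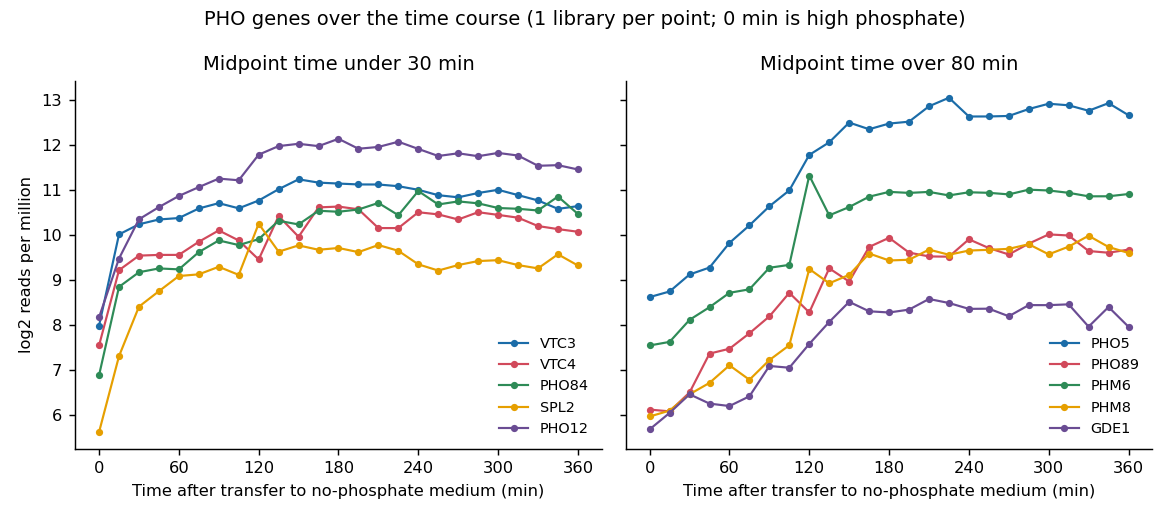
Log2 RPM (vertical axis) against time in min for 5 PHO genes with early midpoints (left) and 5 with late midpoints (right), with 1 library per point. PHO84 rises from 6.88 at 0 min to 8.85 at 15 min, whereas PHO5 goes from 8.62 at 0 min to 8.74 at 15 min and reaches 12.50 at 150 min.

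**Figure D3:**
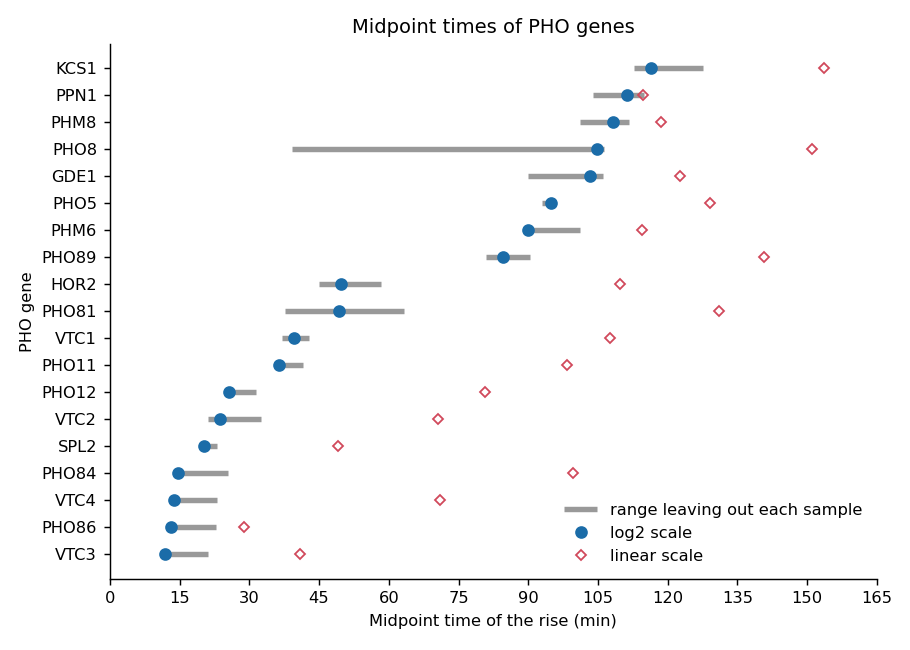
Midpoint times in min of the 19 PHO genes listed in all 25 samples, on the log2 scale (filled points, with grey bars for the range when each sample is left out in turn) and on linear ratios (open diamonds). The log2 midpoints run from 11.8 min for VTC3 to 116 min for KCS1, and the diamonds lie later for every gene shown.

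Late samples (315 to 360 min) were then tested against early ones (15 to 60 min), a contrast that leaves out the high-phosphate library. All 19 tested members of the PHO regulon rose (all 19 also when adjusted over the list alone), by a median of 1.48 log2 units. The largest rise was that of PHO5 (chromosome II, 429548 to 430951, build R64), which went from 9.24 ± 0.45 to 12.81 ± 0.12 (SD, n = 4), a change of 3.57 (SE 0.22, limma adjusted p = 2.32e-13). It was followed by PHM8 (chromosome V, 225889 to 226854), a phosphatase of lysophosphatidic acid and nucleotides, with 3.17 (SE 0.33, adjusted p = 6.46e-08), PHO89 (chromosome II, 796798 to 798522) with 2.88 (SE 0.24, adjusted p = 3.05e-10) and PHM6 (chromosome IV, 1022007 to 1022321) with 2.68 (SE 0.34, adjusted p = 9.31e-07). PHO84 (chromosome XIII, 24037 to 25800), already high in the early window, went from 9.13 ± 0.19 to 10.61 ± 0.17, a change of 1.48 (SE 0.13). The smallest rises were 0.44 (SE 0.13) for PHO86, 0.48 (SE 0.12) for VTC3 (chromosome XVI, 514511 to 517018) and 0.68 (SE 0.13) for VTC2. The other changes were 1.96 for GDE1, 1.93 for KCS1, 1.61 for HOR2, 1.59 for PHO11, 1.56 for PHO8, 1.25 for PHO12, 1.11 for PHO81, 1.09 for VTC1, 0.98 for SPL2 (chromosome VIII, 374654 to 375100), 0.86 for PPN1 and 0.73 for VTC4. The median of all 4535 genes moved by 0.33, and relative to that gene PHO86, VTC3 and VTC4 changed by 0.11, 0.15 and 0.40 and no longer passed, so that 16 of 19 remained higher.

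The PHO regulon as a list passed camera with its preset correlation (adjusted p = 2.13e-09), but not when the correlation was estimated (adjusted p = 0.214 with an estimated correlation). Among its parts 3 of 3 tested phosphate uptake genes rose, over all genes and when adjusted over the list alone (GIT1 was not tested; camera adjusted p = 0.00348, and 0.252 with an estimated correlation), as did 3 of 3 secreted acid phosphatases (adjusted p = 0.00136, and 0.268 with an estimated correlation). The same held for 4 of 4 internal phosphatases (adjusted p = 4.81e-04, and 0.213 with an estimated correlation) and 5 of 5 polyphosphate genes, whose list did not pass (adjusted p = 0.0636). Of 9 tested signalling components 8 rose (9 when adjusted over the list alone), among them PLC1, phospholipase C, by 2.11 (SE 0.21), KCS1, an inositol phosphate kinase, by 1.93 (SE 0.24), the cyclin gene PHO80 by 1.26 (SE 0.28) and PHO4 itself by 1.22 (SE 0.24). That list passed at an adjusted p of 0.00518 (adjusted p = 0.214 with an estimated correlation). Of the 3 low-affinity phosphate transporters, PHO87 rose by 1.08 (SE 0.28) and PHO91 by 0.44 (SE 0.16), both also when adjusted over the list alone, while PHO90 changed by -0.21 (SE 0.23, limma adjusted p = 0.451) and the list did not pass (adjusted p = 0.903). Relative to the median gene PHO87 alone was higher, PHO90 was lower and PHO91 did not pass. On that scale 3 of 5 polyphosphate genes and 8 of 9 signalling components remained higher.

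The widest fall was that of the ribosomal protein genes, of which 136 of 138 tested fell between the early and the late window (136 when adjusted over the list alone), by a median of -2.53 log2 units, or -2.85 relative to the median gene. RPL8A (chromosome VIII, 35255 to 36025) went from 9.31 ± 0.05 to 5.96 ± 0.79 (SD, n = 4), a change of -3.36 (SE 0.37, limma adjusted p = 1.74e-07). RPL9A changed by -3.17 (SE 0.35), RPL21A by -3.14 (SE 0.44), RPS16B by -2.99 (SE 0.23), RPL16B by -2.97 (SE 0.31), RPS26B by -2.97 (SE 0.37), RPP2A by -2.96 (SE 0.38), RPS9B by -2.95 (SE 0.22) and RPS22A by -2.94 (SE 0.27). YBR191W-A has no coordinates in the reference used here, so overlap with RPL21A could not be examined. Its change of -3.14 (SE 0.44) equals that of RPL21A to the digits given. The same reads may therefore have been counted for both, and they are not separate evidence. Many ribosomal protein genes are pairs of near-identical copies whose reads could be split between them. The 2 that did not pass, named after their values were seen, were RPL15B at 0.18 (SE 0.18) and RPP1 at -0.14 (SE 0.27), and RPP1 entered the list by its name but encodes a subunit of RNase P. The list passed camera at an adjusted p of 1.58e-164 with the preset and 0.048 with an estimated correlation. Ribosomal protein genes held 32.1% of reads in high phosphate, 28.9% at 15 min, 26.5% at 105 min, 22.4% at 120 min, 13.5% at 135 min and 8.01% at 150 min. The median of the list crossed the midpoint of its fall at 138 min (135 to 141 when each sample was left out in turn). From 195 to 360 min the percentage lay between 3.92% and 7.22% and was higher in shallower libraries. Pearson r was 0.90 against the reciprocal of depth (permutation p = 0.00014, adjusted over 3 relations 0.00042). Spearman rho was 0.91 (permutation p = 0.00018, adjusted 0.00054), and r was 0.80 without the 2 samples farthest from the median (n = 12).

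The rises at 315 to 360 min were led by stress-induced genes. Of 44 tested genes of the environmental stress response 40 rose (40 when adjusted over the list alone), by a median of 1.82 log2 units, or 1.49 relative to the median gene. HSP26, a small heat-shock protein (chromosome II, 382030 to 382674), went from 7.08 ± 0.11 to 12.21 ± 0.30 (SD, n = 4), a change of 5.12 (SE 0.37, limma adjusted p = 2.22e-10). GRE1 changed by 4.65 (SE 0.27), SIP18 by 4.54 (SE 0.36) and CTT1, the cytosolic catalase, by 4.27 (SE 0.34). The other genes among the 10 highest were YCL048W-A at 4.90 (SE 0.26), YMR175W-A at 4.69 (SE 0.36), HPF1 at 4.37 (SE 0.23), FMP16 at 4.17 (SE 0.30), YHR033W at 4.06 (SE 0.26) and GND2 at 3.98 (SE 0.19). YMR175W-A lies next to SIP18 on chromosome XIII, so their reads could be shared. The list passed camera (adjusted p = 1.15e-24, and 0.184 with an estimated correlation). Of 17 trehalose and glycogen genes 15 rose (16, with 1 lower, when adjusted over the list alone). GPH1, glycogen phosphorylase, stood at 2.93 (SE 0.20), PIG2 at 2.87 (SE 0.26), GLC3 at 2.58 (SE 0.28) and PGM2 at 2.50 (SE 0.35). Camera passed this list (adjusted p = 3.08e-05, and 0.268 with an estimated correlation). Of 22 heat-shock chaperones 8 rose and 6 fell (8 and 7 when adjusted over the list alone), with HSP26, SSE2 at 2.07 (SE 0.25), SSA4 at 1.79 (SE 0.23) and HSP104 at 1.73 (SE 0.18) among those that rose, and the list did not pass (adjusted p = 0.903). Its median was -0.06 and its mean 0.46, so the sign depends on the summary. Relative to the median gene 37 of the stress response genes were higher and 0 lower, 13 and 1 of trehalose and glycogen, and 8 and 10 of the chaperones.

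Genes of respiration, nitrogen scavenging and autophagy were higher late. Of 46 genes of the TCA cycle and respiration 41 rose (41 when adjusted over the list alone), by a median of 1.12 or 0.79 relative to the median gene. The largest were SDH2 at 1.72 (SE 0.26), SDH4 at 1.71 (SE 0.20), QCR10 at 1.69 (SE 0.20) and CYT1 at 1.63 (SE 0.15). Respiration as a list passed camera (adjusted p = 2.51e-10, and 0.109 with an estimated correlation). Of 16 genes under nitrogen catabolite repression 15 rose (15 when adjusted over the list alone). They were led by the permeases GAP1 at 3.04 (SE 0.21), AGP1 at 2.42 (SE 0.17) and DUR3 at 2.31 (SE 0.27), followed by DAL3 at 2.06 (SE 0.31). Nitrogen genes as a list passed camera (adjusted p = 1.27e-05, and 0.110 with an estimated correlation). CAR1, arginase, named after its values were seen, fell by 0.81 (SE 0.17, limma adjusted p = 2.22e-04). Of 18 genes of autophagy and vacuolar proteolysis 16 rose (16 when adjusted over the list alone). ATG8 stood at 2.42 (SE 0.20), ATG9 at 2.15 (SE 0.26), ATG19 at 2.03 (SE 0.21) and PRB1, vacuolar proteinase B, at 1.79 (SE 0.23). Autophagy as a list passed camera (adjusted p = 5.91e-07, and 0.109 with an estimated correlation). With the median gene as reference 36 genes of respiration were higher and 1 lower, 12 and 1 under nitrogen catabolite repression, and 15 and 0 of autophagy. The midpoint of the rise was 117 min for the stress response, 115 min for trehalose and glycogen, 122 min for autophagy, 128 min for respiration and 132 min for nitrogen catabolite repression.

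Carbon uptake and glycolysis changed gene by gene. Of 18 glycolysis and fermentation genes 12 rose and 1 fell (13 and 1 when adjusted over the list alone). The glyceraldehyde-3-phosphate dehydrogenase TDH1 rose by 3.62 (SE 0.22), the enolase ENO1 by 2.48 (SE 0.25) and the glucokinase GLK1 by 1.35 (SE 0.17), whereas the hexokinase HXK2 fell by 1.26 (SE 0.13, limma adjusted p = 6.30e-10). The list did not pass (camera adjusted p = 0.0636). Of 5 hexose transporter genes 4 rose (4 when adjusted over the list alone; camera adjusted p = 0.249), with HXT7 at 1.71 (SE 0.23), the regulator STD1 at 0.92 (SE 0.25), HXT1 at 0.72 (SE 0.17) and HXT3 at 0.69 (SE 0.14). Of 8 genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation 6 rose (6 when adjusted over the list alone; camera adjusted p = 0.157), with ALD4 at 1.67 (SE 0.15), ICL1 at 0.89 (SE 0.24), ACS1 at 0.86 (SE 0.25) and FOX2 at 0.85 (SE 0.24). Many of these rises went with the shift of the median gene. Relative to it 5 glycolysis genes were higher and 1 lower, 2 and 1 of the hexose transporters, and 1 and 0 of gluconeogenesis.

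**Figure D4:**
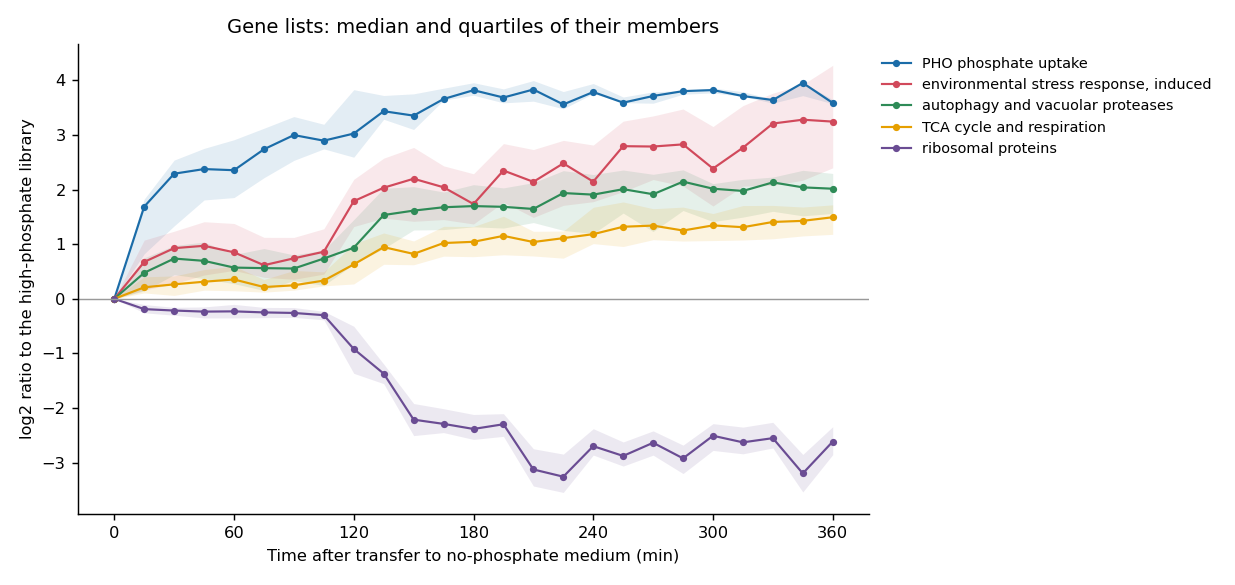
Median log2 ratio to the high-phosphate library (vertical axis, lines, with shading for the quartiles of the members) against time in min for 5 gene lists. Phosphate uptake stands at 1.69 at 15 min, whereas the ribosomal proteins go from -0.30 at 105 min to -2.21 at 150 min, over which time the stress response goes from 0.86 to 2.20.

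Growth-related groups moved less than the ribosomal proteins between the early and the late window. Against high phosphate, ribosome biogenesis genes were already lower in the early window. Their median log2 ratio was -0.68 at 15 to 60 min, -1.15 at 135 to 180 min and -0.81 at 315 to 360 min. In these windows 5 of 77, 48 of 74 and 20 of 75 were at least 2-fold lower. Of 74 ribosome biogenesis genes 9 fell and 3 rose (8 and 2 when adjusted over the list alone), with UTP22 at -1.23 (SE 0.18), NOP1, the nucleolar methyltransferase fibrillarin, at -1.13 (SE 0.25), RRP5 at -0.88 (SE 0.19) and SPB4 at 0.91 (SE 0.20). The list had a median of -0.11, or -0.44 relative to the median gene, against which 30 fell and 1 rose (camera adjusted p = 0.00209, and 0.592 with an estimated correlation). Of 32 proteasome genes 3 fell and 1 rose (1 and 0 when adjusted over the list alone), namely RPT6 at -0.45 (SE 0.13), PRE1 at -0.42 (SE 0.14), PRE4 at -0.40 (SE 0.17) and PUP2 at 0.42 (SE 0.15). Camera placed the proteasome lower (adjusted p = 0.0205, and 0.447 with an estimated correlation). Against high phosphate the proteasome median was 0.36 at 15 to 60 min and 0.19, at percentile 41.5, at 315 to 360 min. Of 21 G1/S genes 6 fell and 2 rose (5 and 1 when adjusted over the list alone). The replication clamp gene POL30 stood at -1.06 (SE 0.15), GIC2 at -0.96 (SE 0.21), TOS4 at -0.77 (SE 0.26) and CDC9 at -0.70 (SE 0.28). The G1/S list was lower by camera (adjusted p = 0.00402, and 0.268 with an estimated correlation). Of 26 genes of G2/M and M/G1 18 rose (18 when adjusted over the list alone). These included the daughter-cell genes SCW11 at 1.81 (SE 0.17), DSE1 at 1.62 (SE 0.22) and DSE4 at 1.60 (SE 0.16), and the cyclin gene PCL9 at 1.42 (SE 0.19). The G2/M list was higher by camera (adjusted p = 0.00229, and 0.109 with an estimated correlation). Of 17 sulfur and methionine genes 6 fell and 4 rose (6 and 4 when adjusted over the list alone), with the S-adenosylmethionine synthetases SAM2 at -2.53 (SE 0.19) and SAM1 at -2.11 (SE 0.21), CYS3 at -1.72 (SE 0.20) and MET6 at -1.37 (SE 0.15). That list had a median of 0.10 but a mean of -0.34, and camera gave it as lower (adjusted p = 0.00209, and 0.048 with an estimated correlation). Set against the median gene 0 proteasome genes were higher and 20 lower, 0 and 15 of G1/S, 13 and 1 of G2/M and M/G1, and 0 and 7 of sulfur and methionine, so the counts of these lists depend on that scale.

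Over all genes, limma called 2167 of 4535 between the early and the late window, 1713 higher and 454 lower, of which 672 and 199 changed at least 2-fold. With each sample centred on its median gene 1844 were called, 876 higher and 968 lower, so that the share of higher calls went from 79.1% to 47.5%, and with quantile normalization 1623 were called, 849 higher and 774 lower. Of 32 lists tested, 16 passed camera with the preset correlation, and of 30 that could be run with an estimated correlation 2 passed, ribosomal proteins and sulfur and methionine.

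The successive windows showed when these changes took place. Between 15 to 60 and 75 to 120 min, 32 genes were called (18 higher and 14 lower). The highest were PHO5 at 1.67 (SE 0.22, limma adjusted p = 1.67e-04), PHM6 at 1.47 (SE 0.34, adjusted p = 0.0442) and PHO89 at 1.40 (SE 0.24, adjusted p = 0.00289). PHM6 stood at 8.79, 9.27 and 9.34 log2 RPM from 75 to 105 min and at 11.32 at 120 min, so its change leans on that shallow library. The lowest were BTN2 at -1.28 (SE 0.26), YPR036W-A at -1.18 (SE 0.19) and PYC1, pyruvate carboxylase, at -1.15 (SE 0.27). Between 75 to 120 and 135 to 180 min 1205 genes were called (898 higher and 307 lower), led by GND2 at 2.28 (SE 0.19, adjusted p = 5.37e-10), YBR285W at 2.25 (SE 0.34) and the glycogen debranching enzyme GDB1 at 2.23 (SE 0.26). At the lower end were RPS29A at -2.15 (SE 0.18), RPS26B at -2.06 (SE 0.37) and RPS8B at -2.04 (SE 0.24). Between 135 to 180 and 195 to 240 min 40 genes were called (9 higher and 31 lower), with DBP7 at 0.97 (SE 0.24), GZF3 at 0.96 (SE 0.22) and HPF1 at 0.95 (SE 0.23) highest. The lowest there were RPS9A at -1.21 (SE 0.21), ASC1 at -1.18 (SE 0.26) and RPS13 at -1.17 (SE 0.25). From 195 to 240 to 255 to 300 min 7 genes were called, YCL048W-A at 1.75 (SE 0.26), DSE1 at 1.18 (SE 0.22), DDR2 at 1.08 (SE 0.21), DSE2 at 0.97 (named after its values were seen), CUE4 at -0.94 (SE 0.19), SUR2 at -0.89 (SE 0.19) and SAM2 at -0.88 (SE 0.19). From there to 315 to 360 min 4 genes were called, the stress genes GRE1 at 1.41 (SE 0.27), NQM1 (SE 0.26, adjusted p = 0.0241) and ALD3 at 1.18 (SE 0.23), and POL30 at -0.75 (SE 0.15).

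At an unadjusted p under 0.05 the 5 successive contrasts gave 464, 1693, 627, 418 and 286 genes. Centred on the median gene the split of higher against lower calls was 16 and 12, 366 and 529, 7 and 14, 3 and 2, and 3 and 1. With quantile normalization it was 9 and 11, 590 and 327, 24 and 49, 7 and 0, and 5 and 2. Single samples moved 4 of these counts by over 1.5 times. For 75 to 120 against 15 to 60 min they were 18, 15, 21, 20 and 20 without the 15, 30, 45, 105 or 120 min sample. For 195 to 240 against 135 to 180 min they were 3, 67, 163, 4 and 3 without the 135, 180, 195, 210 or 225 min sample. For 255 to 300 against 195 to 240 min they were 1, 3, 31, 15 and 1 without the 210, 225, 240, 255 or 285 min sample. For 315 to 360 against 255 to 300 min they were 0, 0, 13, 1 and 0 without the 255, 270, 315, 345 or 360 min sample. The 1205 genes between 75 to 120 and 135 to 180 min became 1665 without the 120 min sample, within 1.5 times, and 2020 with array weights.

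A spline of time over all 24 no-phosphate samples found a course in 2665 of 4535 genes (58.8%, limma F test), of which 1991 ended higher and 674 lower. The fitted range was at least 2-fold for 1445 genes and at least 4-fold for 337. PHO5 had an adjusted p of 7.82e-25, PHO89 of 8.26e-20, PHM8 of 8.04e-18, PHO84 of 2.76e-15, HSP26 of 1.12e-14, RPL8A of 5.24e-11, SPL2 of 3.80e-10 and VTC3 of 5.19e-09. PHO84 had window means of 9.13, 9.80, 10.40, 10.67, 10.68 and 10.61 in order, and PHO5 of 9.24, 10.91, 12.35, 12.77, 12.75 and 12.81. VTC3 stood highest at 135 to 180 min, with 11.14 ± 0.09, and was at 10.72 ± 0.14 by 315 to 360 min (SD, n = 4). RPL8A had a mean of 9.31 at 15 to 60 min and of 7.02, 5.86, 6.29 and 5.96 in the 4 windows from 135 min on. HSP26 had window means of 7.08, 7.99, 9.63, 10.68, 11.54 and 12.21.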

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

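The tests in this part of the 120 min library, of the reads outside ribosomal proteins, of foreign reads in general and of other splits of the samples were chosen only after the results were seen. Those of GC content and length, of the floor and of reads with an early profile were set before.

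Of 198 groups of 4 samples, the samples of 1 window for 1 measure, 20 had a highest or lowest sample far from the other 3, where chance gives about 1 in 20, or 9.9. The 120 min sample accounts for 5 of them, with 3261 genes listed against 4973 to 5311 in the others of its window and 14.9% of reads in the 10 most abundant genes against 11.7% to 11.9%. It also had a ribosomal protein median of -0.92 against -0.30 to -0.25, SPL2 at 10.25 against 9.11 to 9.29 and VTC2 at 9.36 against 9.03 to 9.08. The 135 min sample stood apart with 13.5% ribosomal protein reads, a ribosomal protein median of -1.37 and PHO11 at 11.32. In the first window the 60 min sample had a depth of 0.75 (in units of 1000000 reads), 4822 genes listed and KCS1 at 6.61, and the 15 min sample had a phosphate uptake median of 1.69 and VTC4 at 9.22. The 195 min sample listed 4325 genes. The stress response had a median of 2.39 at 300 min and of 2.77 at 315 min. The 345 min sample had a depth of 1.496 in the same units and a ribosomal protein median of -3.20, and the 360 min sample a polyphosphate median of 2.33 and VTC1 at 11.39. Genes specific to the other mating type, which a strain of mating type a should not transcribe much, reached 21 reads for MF(ALPHA)1, 28 for SAG1 and 52 for STE3 in the library that lists the most.

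The first pattern is the excess of higher over lower calls late in the course. A candidate explanation is that ribosomal proteins, which held 28.9% of reads at 15 min and 5.88% at 360 min, left room that other genes share. With each sample scaled to its reads outside ribosomal proteins, the median change of 4397 other tested genes was -0.0498, against 0.35 for the same genes before. After the scaling 1710 genes were called, 778 higher and 932 lower. That scaling took 0.396 to 0.405 off every gene, which is more than the median change of 0.35 before it. The percentages already fix this amount, so the test could not decide and the explanation stays open. Whether the cells also held less RNA in total is not answered by values that sum to a fixed amount.

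The second pattern is the number of genes called between 75 to 120 and 135 to 180 min. The count does not rest on the shallow 120 min library, since 1665 genes were called without that library and 1205 with it. Leaving it out does not isolate depth, because that sample also lay part-way through the fall of the ribosomal proteins. Their percentage was 26.5% at 105 min, 22.4% at 120 min and 13.5% at 135 min. What low depth by itself did to the count is therefore not separated. After each sample's trend on GC content and gene length was taken out, 893 genes were called against 1191 before among 4458 genes with both values, and 716 were called both times. Such a trend could not be the whole cause. The split of higher and lower turned to 415 and 478, but this step also takes out each sample's overall offset. Median centring alone, over all 4535 tested genes, gave 895 genes, 366 higher and 529 lower. The part due to GC content and gene length is therefore not separated from that of centring. Time without phosphate stays open as the biological explanation and was not tested, since time and the order of sampling are the same in 1 course.

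The third pattern is the spread of the ribosomal protein percentage from 3.92% to 7.22% over the 12 samples from 195 to 360 min, which went with the reciprocal of depth. The range of samples was chosen after the percentages were seen. The floor on low values does not account for it, since the highest over lowest percentage was 1.78 among genes listed in all 25 samples and 1.84 among all. A straight line gave an intercept of 3.05% (SE 0.38) and 15649 further ribosomal protein reads per library (SE 2423), as a fixed number of reads from other libraries could give. For such reads in general, the percentage of genes at least 2-fold higher late was related to the reciprocal of depth in the 7 samples at 15 to 105 min with r = 0.31 (exact p = 0.529) and rho = 0.68 (exact p = 0.11), and r = 0.07 without the 2 farthest. For reads with an early profile, the percentage held by 151 other genes lower late, 4.27% to 5.83%, gave r = 0.47 (permutation p = 0.126) and rho = 0.24 (permutation p = 0.441) in the 12 samples, and r = -0.29 without the 2 farthest, so neither test decides and both stay open beside a true difference between samples.

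Other splits of the 8 samples into 4 and 4 gave at most 1 gene for the late contrast against 2167, and 9 against 32 for 75 to 120 and 15 to 60 min. They gave at most 3 against 7 for 255 to 300 and 195 to 240 min, and 0 against 4 for 315 to 360 and 255 to 300 min. In each of these 4 contrasts 1 of 35 splits, the real one, reached the count, so chance can be excluded at that level. For 135 to 180 and 75 to 120 min the real split was also 1 of 35, with 1205 genes, but the split that puts the 120 min sample with 150 to 180 min gave 1096. For 195 to 240 and 135 to 180 min 3 of 35 splits gave 40 genes or more, so chance cannot be excluded. The split that puts 195 min with 135, 165 and 180 min gave 214, the highest count, and a reason for it was not tested. For the spline 1 of 100 orders of the times, the real one, gave 2665 genes and the highest of the others 42.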

How the results depend on the processing

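Leaving out samples in successive contrasts, leaving out 120 min for late against early, leaving out 120 and 135 min together, setting unlisted values to the floor and weights from recovered reads were chosen after seeing the data. The count of 2167 genes late against early stayed within 1.5 times (1571 to 2566) and the spline count of 2665 (1980 to 3106) under all alternatives but a floor of 50 reads, which gave 1116 and 1381 because 1816 genes were tested in place of 4535. For the first, leaving out each of the 8 samples compared gave 1932 to 2050 and leaving out 120 min, which lies outside the contrast, 2356. For the spline, leaving out each of the 24 samples gave 2473 to 2825. The 1205 genes between 75 to 120 and 135 to 180 min stayed within 1.5 times except for 2020 with array weights. The other successive counts, 32, 40, 7 and 4 in order of time, rest on few genes, and where no reason is given the cause was not tested. Quantile normalization gave 20 for the first, 73 for the second and 7 for the last. Median centring gave 21 for the second, and leaving out 120 and 135 min 22. For the third, no filter gave 11 and genes listed in all samples 12. A floor of 50 reads gave 113 for the second and 15 for the third, with fewer genes tested. A fit without trend and robustness gave 4 for the second and 3 for the third. Whitening gave 20, 4, 1 and 0, with fitted serial correlations of 0.08 (windows) and 0.13 (spline). Array weights, which gave 120 min the lowest weight, 0.11, returned 81, 163, 52 and 44. Weights from recovered reads gave 72, 29 and 12 for the last 3, and unlisted values at the floor 0 for the last. Leaving out each sample in turn gave 15 to 39, 3 to 163, 1 to 31 and 0 to 13.

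Against high phosphate, the 15 min sample as baseline gave 41 and 66 genes in the first 2 windows against 142 and 168, a 1.5-fold threshold gave 662, 654, 2004, 2017, 2254 and 2286 in the 6 windows, and a 4-fold threshold 7, 14, 202, 298, 352 and 395. An estimated correlation passed 2 of 30 lists where the preset passed 16 of 32, while fry passed 24 of 30, 14 of them also passed by camera. For genes of mating type a camera pointed down without passing and fry pointed up (adjusted p = 0.0378). Both can hold, since the list median of 0.21 lies above no change and below the 0.33 of all genes. The median midpoint of 49.4 min became 21.1 min at 25% of the way, 116 min at 75%, 110 min on linear ratios and 66.6 min with the mean of 0 and 15 min as baseline. The ribosomal protein time of 138 min became 117 min at 25%, 188 min at 75% and 119 min on linear ratios. Of 143 named genes called late against early, 117 kept the call under all of up to 22 alternatives, 26 lost it under at least 1 and 0 reversed. PHO86, SPL2, VTC3 and VTC4 lost it under 1 each, and PRE4 (10), PHO91 (9), CDC9 (7), FIG2 (6) and HHO1 (5) under the most. Depth limits low genes, with a counting SD of 0.46 log2 units at 10 reads and 1057 listed genes left untested.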

Other observations

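The direction reversals, pairs and genes listed in a single window described in this part were noticed after the data were seen, and no explanation was tested for them.

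Biosynthetic pathways changed in parts between 15 to 60 and 315 to 360 min. Of 38 Gcn4 amino acid synthesis genes 17 rose and 4 fell (17 and 5 when adjusted over the list alone). CPA1 stood at 1.95 (SE 0.15, limma adjusted p = 1.54e-12), HIS4 at 1.82 (SE 0.16), ARG5_6 at 1.55 (SE 0.22) and ARG1 at 1.48 (SE 0.22). The list had a median of 0.30, or -0.03 relative to the median gene, with 9 higher and 10 lower on that scale, and did not pass camera (adjusted p = 0.555). Of 16 purine genes 8 rose and 2 fell (8 and 2 when adjusted over the list alone; camera adjusted p = 0.903). The 2 that fell both encode inosine monophosphate dehydrogenases, IMD2 at -1.94 (SE 0.25) and IMD4 at -0.96 (SE 0.19). MTD1 changed by 1.67 (SE 0.21) and ADE17 by 1.44 (SE 0.19). Of 24 ergosterol genes 12 rose (13 when adjusted over the list alone). The methyl sterol oxidase gene ERG25 stood at 2.01 (SE 0.14), ERG1 at 1.24 (SE 0.15), ERG5 at 1.22 (SE 0.14) and ERG11 at 0.95 (SE 0.13), and the list did not pass (adjusted p = 0.0984). Of 16 phospholipid synthesis genes 6 fell and 3 rose (6 and 4 when adjusted over the list alone; adjusted p = 0.102). The phosphatidate phosphatase gene PAH1 rose (SE 0.29, adjusted p = 0.00114), as did PSD2 at 1.15 (SE 0.22), and the changes were negative for the inositol transporter ITR1 at -0.98 (SE 0.20) and CHO1 at -0.74 (SE 0.17). Of 8 zinc genes 5 rose (5 when adjusted over the list alone; adjusted p = 0.491), with ZAP1 at 1.32 (SE 0.29), IZH1 at 1.15 (SE 0.23), DPP1 at 0.82 (SE 0.18) and IZH2 at 0.60 (SE 0.16). Of 13 iron genes 2 rose (1 when adjusted over the list alone; adjusted p = 0.650), ATX1 at 1.10 (SE 0.38) and ARN2 at 0.83 (SE 0.24), while CTH1 at 0.57 (SE 0.26) and HMX1 at 0.55 (SE 0.33) did not pass. Relative to the median gene 4 purine genes were higher and 6 lower, 6 and 4 of ergosterol, 2 and 8 of phospholipid synthesis, 3 and 1 of zinc, and 0 and 3 of iron.

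The copies of the genes for histones H3 and H4 moved apart, although part of the rises is the shift of the median gene. HHT1 and HHF1, divergent neighbours on chromosome II, changed by 0.58 (SE 0.15) and 0.57 (SE 0.15), and HHF2 and HHT2 by -0.69 (SE 0.15) and -0.43 (SE 0.14), respectively. HHT2 was named after its values were seen, and the copies encode the same proteins. Relative to the median gene 0 of the 10 histone genes rose and 4 fell. HHO1 rose by 0.49 (SE 0.18). In all 3 of 10 histone genes rose and 3 fell (3 and 3 when adjusted over the list alone; camera adjusted p = 0.408). Of 6 genes specific to mating type a, MFA1 rose by 0.93 (SE 0.16), MFA2 rose by 0.48 (SE 0.16) and BAR1 fell by 0.51 (SE 0.17). STE6 at -0.35 (SE 0.26) did not pass (2 higher and 1 lower also when adjusted over the list alone; adjusted p = 0.899). Of 10 pheromone response genes FIG2 rose by 0.88 (SE 0.31), and 0 passed when adjusted over the list alone (adjusted p = 0.415), with PRM2 at 0.68 (SE 0.33), FUS1 at -0.46 (SE 0.20) and SST2 at -0.26 (SE 0.22) not past the test. Of 2 meiosis genes tested NDT80 rose by 1.14 (SE 0.33) and DIT1 at 0.50 (SE 0.23) did not pass, although both passed when adjusted over the list alone. Among 13 housekeeping genes 2 rose and 2 fell (2 and 2 when adjusted over the list alone; adjusted p = 0.285). The translation elongation factor genes TEF2 and TEF1, near-identical copies, changed by -1.47 (SE 0.22) and -1.02 (SE 0.21), and KRE11 at -0.55 (SE 0.28) and TFC1 at 0.49 (SE 0.21) did not pass. Set against the median gene 1 gene of mating type a was higher and 2 lower, 0 and 3 of the pheromone response, 1 and 0 of meiosis, and 0 and 3 of housekeeping.

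Some genes were listed in one of the outer windows and not the other, and were not tested. Of these, 19 were listed in all 4 samples at 315 to 360 min and in none at 15 to 60 min. GIT1 of the PHO regulon had a late mean of 6.69 log2 RPM, at least 3.49 above the mean early floor, and it was first listed at 75 min with 19 reads. Named after their values were seen, the hexose transporter HXT5 had a late mean of 7.92, the NADH dehydrogenase NDE2 of 6.45, the proline permease PUT4 of 6.44, the sporulation gene SPS100 of 5.35 and the thiolase POT1 of 4.82. In the other direction 5 genes were listed early and not late, with early means of 3.63 to 3.85. These lie below the floors of 4.01 to 4.30 at 315, 330 and 360 min but above the floor of 2.74 at 345 min. At 345 min the comparison rests on a single sample and few reads, so whether depth accounts for their absence stays open.

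The distance between neighbouring samples, over the 1000 genes with the highest mean and with counting noise subtracted, was 0.38 from 0 to 15 min, 0.11 to 0.20 between neighbours from 15 to 105 min, 0.68 from 105 to 120 min. It was 0.55 from 120 to 135 min, 0.48 from 135 to 150 min and 0.34 from 150 to 165 min. Both steps that involve 120 min include the shallowest library. Later steps of over 0.30 were 0.45 from 195 to 210 min, 0.39 from 225 to 240 min, 0.34 from 330 to 345 min and 0.35 from 345 to 360 min. Over these later steps the ribosomal protein median went from -2.30 to -3.12, -3.26 to -2.70, -2.55 to -3.20 and -3.20 to -2.61, respectively. The percentage of reads on ribosomal protein genes was related to depth from 195 to 360 min.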
